A study of Rattus norvegicus with 23 samples.

How the data were processed

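Liver RNA was sequenced from 23 rat offspring at postnatal day 48. Their dams had inhaled filtered air (0 ppm ozone) or 0.8 ppm ozone on gestation days 5 and 6, per the series design. The labels' treatment protocol also describes chamber exposures of a subset of rats without saying which. Every library name carries an ozone level of 0 ppm, and it was assumed here that no offspring of the series had inhaled ozone; if some had, the ozone contrasts would not measure the maternal exposure alone. The groups, taken from the labels, were female air (n = 6), female ozone (n = 6), male air (n = 6) and male ozone (n = 5). Library names fell into 2 styles with overlapping sample numbers, treated here as 2 sample sheets, a technical batch. Sheets 1 and 2 held 5 and 1 of the female air libraries, 1 and 5 of the female ozone libraries, 3 and 3 of the male air libraries and 4 and 1 of the male ozone libraries. The labels did not assign offspring to dams, so offspring of the same dam cannot be recognised. The p-values treat each animal as independent and would be too small if littermates were present.

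The deposited table held estimated counts for 18056 Ensembl gene identifiers and 23 libraries. Of its values, 19.8% differed from a whole number by more than 1e-06, and 66.8% of genes had whole values in every library. Per the submitters' processing notes, the tools used were STAR 2.6.1d, Partek and DESeq2 and the genome build was rn6; the annotation and the counting settings are not given in the sources used here. Fractional values arise where reads are divided between genes or copies, and such genes are described as uncertain. Total counts per library lay between 8000498 and 15594817. The 10 most abundant genes of a library took between 22.32% and 26.04% of its counts. The number of counts limits the precision for genes of low abundance.

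The table does not pair identifiers with gene names. The RefSeq gene table at hand (assembly GRCr8, 47357 genes) carried 0 Ensembl identifiers, so 0 of the 18056 identifiers could be paired with a symbol. Gene lists fixed before the data were examined (male-higher and female-higher liver genes, growth hormone signalling, xenobiotic metabolism and others) were therefore not tested, and no gene is named by symbol. Gene groups were instead defined by the sex difference in air offspring. The rule for named genes, fixed at the same time, took the genes with the largest log2 rise and fall past the threshold with a gene symbol and a mean of at least 1 CPM in the higher group. Its requirement of a symbol could not be met, so it was applied to identifiers and shortened to 2 per direction in the comparison of males.

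Estimated counts were rounded to whole numbers and analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the groups, which left 12792 genes with 99.91% of the counts. Libraries were scaled with TMM factors, between 0.941 and 1.054. A quasi-likelihood model with a mean for each of the 4 groups and a sample sheet term was fitted to all libraries (5 coefficients, 18 residual degrees of freedom). Contrasts were ozone minus air within each sex, female minus male within each maternal exposure, and the difference of the ozone effects between the sexes. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Log2 CPM values used a prior count of 2. The sheet term itself passed the threshold in 3 genes, and 687 had an unadjusted p below 0.05. Pairs of libraries of the same group (55 pairs) differed by a chi-square of 13.7 to 90.7 per degree of freedom over genes, so no library was a copy of another.

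A sex score placed each liver between the sexes. For each animal, genes that differed by sex among the other 22 animals (adjusted p below 0.05, at least 2-fold, without use of treatment labels) formed the axis. The score was the mean log2 CPM of female-higher genes minus that of male-higher genes, scaled so that the other males averaged 0 and the other females 1. Each axis held 273 to 353 female-higher and 296 to 387 male-higher genes. The treatment coefficient, with the sheet as a covariate, was tested by a two-sided exact permutation within sheets. The covariance across genes of the sex difference and the ozone effect was computed with the 6 male air libraries split 3 and 3 between the differences, over all 20 ways. The share of the sex difference crossed by ozone animals used gene bins set on 3 female and 3 male air libraries and both differences from the other 3 and 3; this computation was chosen after the sex score had been seen. Because simulated genes vary independently, the share of sex-dependent genes moving toward the other sex was also tested by permuting whole animals within sheets.

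On counts simulated for the 12792 genes with known changes, the comparison of males called 31.3%, 77.6% and 92.4% of genes changed 1.5-, 2- and 4-fold, and 10.1% of its calls were unchanged genes. The comparison of females called 14.9%, 70.1% and 97%, with 1.6% of calls on unchanged genes. With males simulated unchanged, the sex score effect was 0.0077. With males simulated a share of 0.3 of the way to the female level, the sex score effect was 0.3645 and the split covariance gave a share of 0.303.

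Alternatives were DESeq2 size factors as scaling, DESeq2 1.42.0 as the tool, no filter on low counts, a mean of at least 1 CPM, no sheet term, limma 3.58.1 voom with quality weights, a fit on the groups compared alone, a minimum change of 1.5-fold, sheet 1 alone, and leaving out each library in turn. Every column of the table was used. Figures were drawn with Python 3.11.15 and matplotlib.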

Results

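Poly(A) RNA of 23 livers was compared between male and female rat offspring, aged 48 days, of dams that inhaled filtered air or 0.8 ppm ozone on gestation days 5 and 6. The 4 groups held 6 female air, 6 female ozone, 6 male air and 5 male ozone libraries. Mean total counts were 12223748 ± 2811150 in female air, 11602798 ± 1150002 in female ozone, 10743372 ± 1315942 in male air and 11737779 ± 1323546 in male ozone livers (SD). In a principal component analysis, component 1 held 43.3% of the variance and separated the sexes among air livers. Its mean was −42.9 ± 10.8 in female air and 51.2 ± 8.9 in male air livers. The means of both ozone groups lay between these, at −25.8 ± 20.1 for females (up to 7.1) and 21.1 ± 14.5 for males (from 4.9), so the ranges of the ozone groups overlapped. Component 2, with 13.7%, set 4 of the 5 ozone males (29.5 to 42.7) above the ranges of male air (−18.7 to 14.2) and female air livers (−19.4 to 11.1). Male ozone replicate 4 lay at −6.6.

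**Figure D1:**
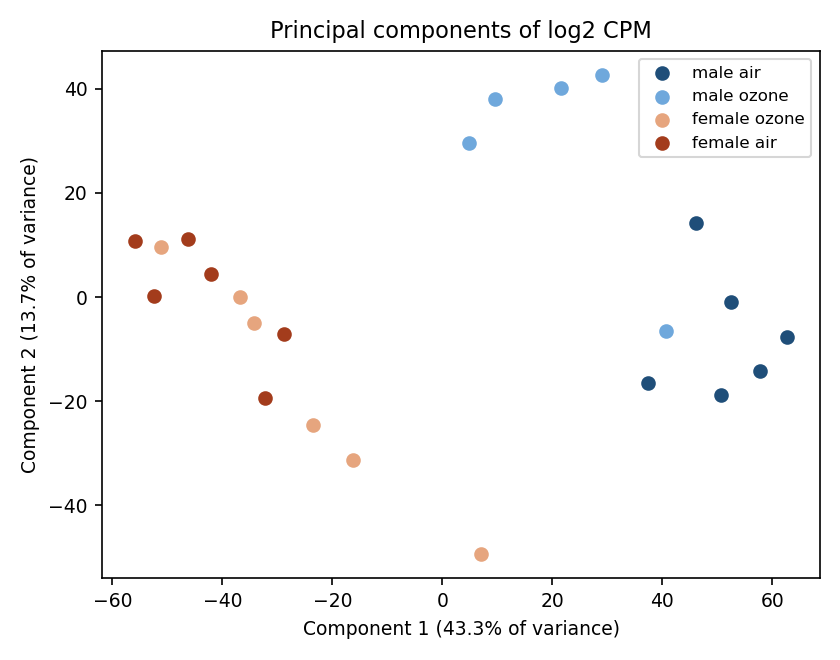
Each point is a liver, placed by principal components 1 (43.3% of variance) and 2 (13.7%) of log2 CPM over the tested genes and coloured by group. The air groups separate on component 1, where the highest ozone female (7.1) passes the lowest ozone male (4.9), and 4 ozone males lie above the other males on component 2.

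The comparison of the sexes in air offspring gives the sex-dependent expression against which the ozone groups can be placed. The livers of the sexes differed over much of the transcriptome: 6183 of 12792 genes (48.3%) differed between female air and male air offspring (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05, n = 6 and 6). Of these, 3042 were higher in females, with a median log2 difference of 0.71 (quartiles 0.50 to 1.03). The other 3141 were higher in males, with a median of −0.74 (quartiles −1.06 to −0.52). A difference of at least 2-fold was seen in 1703. Genes seen in 1 sex alone were few: 4 had at least 1 CPM in every female air liver and at most 3 counts summed over the 6 male air livers, and 7 showed the opposite. By these genes, 0 of the 23 libraries went against the sex on its label. The genes were chosen by the labels of the air livers, so only the ozone libraries were checked. Among sheet 1 libraries alone, 4598 genes differed by sex, a setting added after the data were seen.

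The title of the series speaks of a feminized profile in males, so the effect of maternal ozone was first examined in male offspring. In ozone males 926 genes rose and 735 fell relative to air males, a total of 1661 of 12792 (edgeR, adjusted p below 0.05, n = 5 and 6). The median log2 change was 0.68 among those that rose and −0.68 among those that fell, and 285 changed at least 2-fold. Nearly all changed genes with a sex difference had moved toward the level of air females: 1489 did so, 3 moved away and 169 had no sex call. Of the 3042 female-higher genes 820 rose and 0 fell; independent lists would give 220 and 175. Of the 3141 male-higher genes 3 rose and 669 fell, where independent lists would give 227 and 180. Both lists subtract the same male air livers, which pushes genes on both to the same sign. Independent lists are therefore not a fair baseline. With the male air livers split between the lists, 0 to 819 genes were on both. The median log2 ozone effect in males was 0.40 over all female-higher genes and −0.39 over all male-higher genes. Of the 6609 genes with no sex call, 103 rose and 66 fell. The largest rises included ENSRNOG00000007219, from 0.0542 ± 0.133 CPM in male air to 22.9 ± 29.2 CPM in male ozone livers (adjusted p = 0.0351), and ENSRNOG00000049893, from 0.0493 ± 0.0879 to 6.59 ± 3.42 CPM (adjusted p = 0.00403). The largest falls included ENSRNOG00000049422, from 2.37 ± 2.18 to 0.14 ± 0.268 CPM (adjusted p = 0.0427), and ENSRNOG00000058589, from 2.00 ± 1.46 to 0.214 ± 0.175 CPM (adjusted p = 0.023; SD, n = 6 and 5, edgeR). All 4 identifiers had fractional counts, so reads shared with other genes make their levels uncertain. The call of ENSRNOG00000007219 was lost without any of male air replicates 2 to 6 or male ozone replicates 1 to 3, that of ENSRNOG00000049422 without any of male air replicates 2, 4, 5 and 6 or male ozone replicates 1, 2, 3 and 5, and that of ENSRNOG00000058589 without any of male air replicates 2 and 6 or male ozone replicates 2, 3 and 5. By limma voom ENSRNOG00000007219 had an adjusted p of 0.259, and by DESeq2 ENSRNOG00000049422 had 0.0871 (0.0506 by edgeR without a filter); in sheet 1 alone ENSRNOG00000007219 had 0.0874 and ENSRNOG00000049893 0.071 by edgeR.

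The number of changed genes depended on single animals. The count was 108 without male ozone replicate 2 (the only ozone male of sheet 2), 450, 631 and 823 without male ozone replicates 1, 3 and 5, and 3129 without male ozone replicate 4. It was 1966 without male air replicate 1, and 786, 840, 983, 1093 and 751 without male air replicates 2, 3, 4, 5 and 6. Within sheet 1 (4 ozone and 3 air males) 9 genes passed the threshold. The share of the 6183 sex-dependent genes whose male ozone effect pointed toward the female level was 92.5%, against 57.2% (highest 58.6%) in 20 simulated data sets with unchanged males, the same shared controls and genes that vary independently. Real livers vary along shared axes, so whole animals were also permuted within sheets, on 4745 sex-dependent genes found without treatment labels, a test added after the data were seen. The share was then 80.7% and did not pass (two-sided exact permutation p = 0.0571, 140 arrangements, which gave 18.1% to 82%). From group means without a model it was 93.2%, and between 91.6% and 94.1% with any single male left out. Within sheet 1 it was 91.3%, and within sheet 2, which held 1 ozone male, 86%. Single ozone males set against the air mean gave 90.3%, 85.3%, 92.2%, 65.8% and 88.7% for replicates 1, 2, 3, 4 and 5.

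Male air livers enter both the sex difference and the ozone effect, so the relation was computed again with these controls split. Across genes, which are not independent replicates, the correlation of the female minus male difference with the ozone effect in males averaged 0.534 (0.424 to 0.638 over 20 splits). The covariance averaged 0.2245 (SD 0.0211 over splits), and its highest value in 100 simulated data sets of independent genes without an effect was 0.0107. With whole animals permuted, the covariance with the sex difference over the 4745 genes was 0.1663 (two-sided exact permutation p = 0.0929). With shared controls the covariance was 0.251 against a simulated 0.0288 without an effect, a difference of 0.222. In gene calls with split controls, the count depended on male air replicate 1. In the 10 splits where it served the sex difference, 261 to 1178 genes changed with ozone in males, and in the 10 where it served as a control for ozone, 0 to 105 did. Of the changed genes that also differed by sex, at least 95.8% moved toward the female level in each split that had any; 1 split had none.

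**Figure D2:**
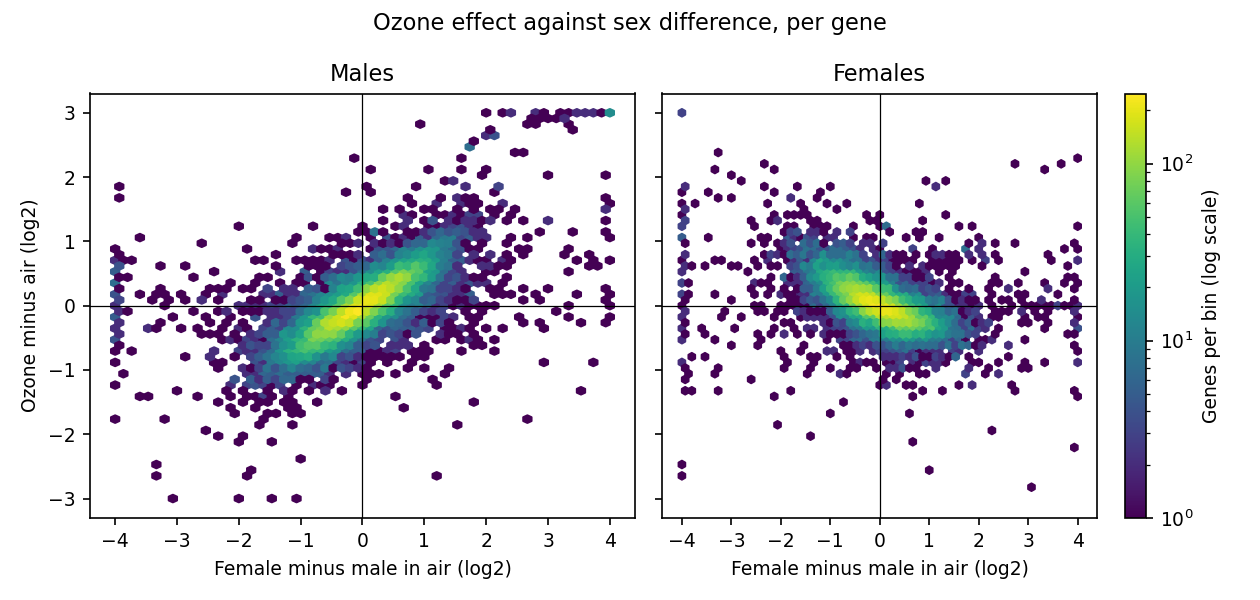
Each panel sets the fitted log2 ozone effect (vertical) against the log2 female minus male difference in air (horizontal) for 12792 genes, males on the left and females on the right, coloured by the number of genes per bin; values beyond 4 (horizontal) or 3 (vertical) are drawn at the edge. The cloud slopes upward in males and downward in females; air livers enter both axes, so part of each slope comes from shared controls.

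The same exposure was examined in female offspring. No gene passed the threshold between ozone and air females by edgeR (0 of 12792, n = 6 and 6); 1293 had an unadjusted p below 0.05, the smallest adjusted p was 0.455, and DESeq2 called 7, of which 5 rose and 2 fell. Over the sex-dependent genes, the median log2 ozone effect in females was −0.19 over the 3042 female-higher genes and 0.26 over the 3141 male-higher genes. In all, 86.6% of the 6183 genes had an effect toward the male level, against 57.2% (highest 58.6%) in 20 simulated data sets with unchanged females, shared controls and independent genes. With whole females permuted within sheets, the share of the 4745 genes was 73.6% and did not stand apart (two-sided exact permutation p = 0.361, 36 arrangements, which gave 17% to 82.5%). With the female air livers split 3 and 3, the correlation across genes of the male minus female difference with the ozone effect in females averaged 0.414 (0.296 to 0.523). The share of genes from group means was 89.7%, and between 82.2% and 91.5% with any single female left out. Single ozone females set against the air mean differed widely, with 84.5%, 92.4% and 86.1% for replicates 3, 4 and 5, and 58.7%, 67.9% and 35.9% for replicates 1, 2 and 6. Sheet 1 held 1 ozone female and sheet 2 held 1 air female, too few for values within sheets.

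The sexes were then compared among ozone offspring. Fewer genes differed between them than in air offspring: 776 of 12792, with 373 higher in females and 403 higher in males (edgeR, adjusted p below 0.05, n = 6 and 5). Such counts also depend on the spread within groups and on the sheets. On component 1 the SD was 20.1 and 14.5 in ozone females and males, against 10.8 and 8.9 in air. Sheets 1 and 2 held 1 and 5 of the female ozone and 4 and 1 of the male ozone libraries. The median log2 female minus male difference of the 3042 female-higher genes was 0.10 in ozone offspring, and that of the 3141 male-higher genes was −0.05. Since both groups of genes were selected on the air livers, part of this drop comes from selection. Of the genes of the 2 groups, 263 and 270 differed by sex in ozone offspring in their air direction and 12 in the opposite one, and 231 of the 776 had no sex call in air. The count was 389 without male ozone replicate 2 and 340 when the ozone groups were fitted alone.

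The ozone effect itself differed between the sexes in 1357 genes (interaction term, edgeR, adjusted p below 0.05), 659 with a higher effect in males and 698 with a lower one. This term equals the sex difference in air minus that in ozone offspring, so it is also the direct test of a changed sex difference. Of the 3042 female-higher genes, 597 had a higher effect in males and 0 a lower one. Among the 3141 male-higher genes, 3 had a higher effect in males and 643 a lower one. The air livers that selected these genes also enter the interaction, which pushes the counts this way. Over the 6183 sex-dependent genes, 93.8% had an interaction with the sign of the sex difference, against 61.3% (highest 62.7%) in 20 simulated data sets of independent genes without an ozone effect. With the air livers of both sexes split 3 and 3 the share was 84.5% to 92.7%, but the median count of interaction calls was 0 (0 to 697 over 20 splits). The interaction count was 0 without female air replicate 2, male air replicate 6 or male ozone replicate 2, and 1 without male air replicate 3. It was 715, 850 and 561 without female air replicates 1, 4 and 5, 727 without male air replicate 2, 558, 640 and 2509 without female ozone replicates 3, 5 and 6, and 403, 508, 468 and 2729 without male ozone replicates 1, 3, 5 and 4.

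A score per animal placed each liver between the sexes (0 for males and 1 for females), on genes that differed by sex at least 2-fold among the other animals. Air males averaged −0.03 ± 0.14 and air females 1.03 ± 0.10 (SD, n = 6 and 6). Ozone males averaged 0.16 ± 0.14 (n = 5) and ozone females 0.89 ± 0.14 (n = 6). The difference between ozone and air males, 0.134 with an SE of 0.073 after the sheet term, did not pass the threshold (two-sided exact permutation within sheets, p = 0.129, 140 arrangements, smallest possible p 0.00714). That between ozone and air females was −0.111 with an SE of 0.10 (exact p = 0.25, 36 arrangements, smallest possible p 0.0278). With axis genes of any fold change, ozone males averaged 0.35 ± 0.23 and air males −0.16 ± 0.14, and the male difference was 0.481 with an SE of 0.118 (exact permutation p = 0.0214). On that axis ozone females averaged 0.79 ± 0.35 and air females 1.10 ± 0.20, and the female difference of −0.249 did not pass (exact p = 0.333). Without male air replicate 3, the male difference on the 2-fold axis was 0.184 (exact p = 0.0333); with sheet 1 alone it was 0.144 (exact p = 0.257).

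**Figure D3:**
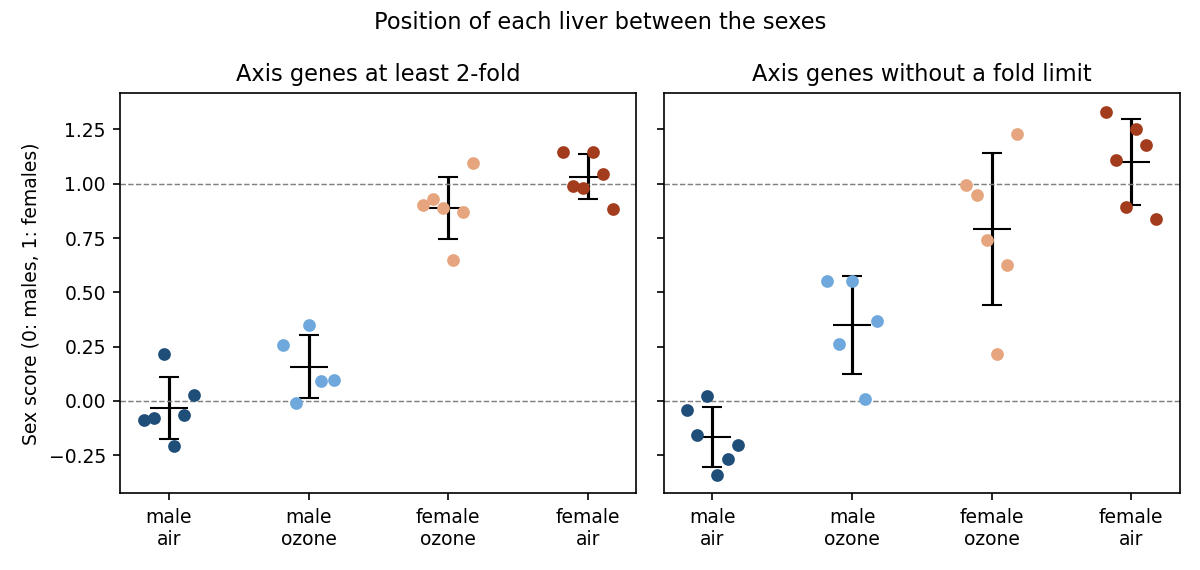
Points are livers, with group means and SD as bars; the vertical axis is the sex score, 0 at the mean of males and 1 at the mean of females, on axis genes of at least 2-fold (left) and of any fold change (right). Ozone males average 0.16 on the left and 0.35 on the right, air males −0.03 and −0.16.

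The part of the sex difference crossed by ozone animals was compared between genes with small and large sex differences. For genes with a sex difference of 1.4 to 2-fold in air offspring, ozone males had moved 55.1% ± 25.4 of the way to the female level, for 2 to 4-fold genes 50.2% ± 21.8, and for genes over 4-fold 21.1% ± 12.4 (SD over 5 animals). The share over 4-fold was the smaller one in 4 of 5 ozone males (not in replicate 4, with 12.1% and 12.8%), with a mean difference from the 1.4 to 2-fold genes of 34 ± 20 percentage points (exact sign-flip permutation p = 0.125; with 5 animals no p under 0.0625 is possible, so this test could not pass). Ozone females had moved 32.2% ± 36.8, 26% ± 31.6 and 9.18% ± 12.5 of the way to the male level (SD over 6 animals), with the smaller share over 4-fold in 5 of 6 (not in replicate 6; exact sign-flip permutation p = 0.0938). Over the 11 ozone animals of both sexes together, a test added after the data were seen, the share over 4-fold was smaller in 9, by 28 ± 22.6 points (two-sided exact sign-flip permutation p = 0.00586). All animals were set against the same air livers, so their differences are not independent and these p-values may be too small. Animals varied widely: male ozone replicate 4 had crossed 12.1% of the 1.4 to 2-fold differences and male ozone replicate 1 74.5%, female ozone replicate 6 −13.4% and female ozone replicate 4 89%.

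**Figure D4:**
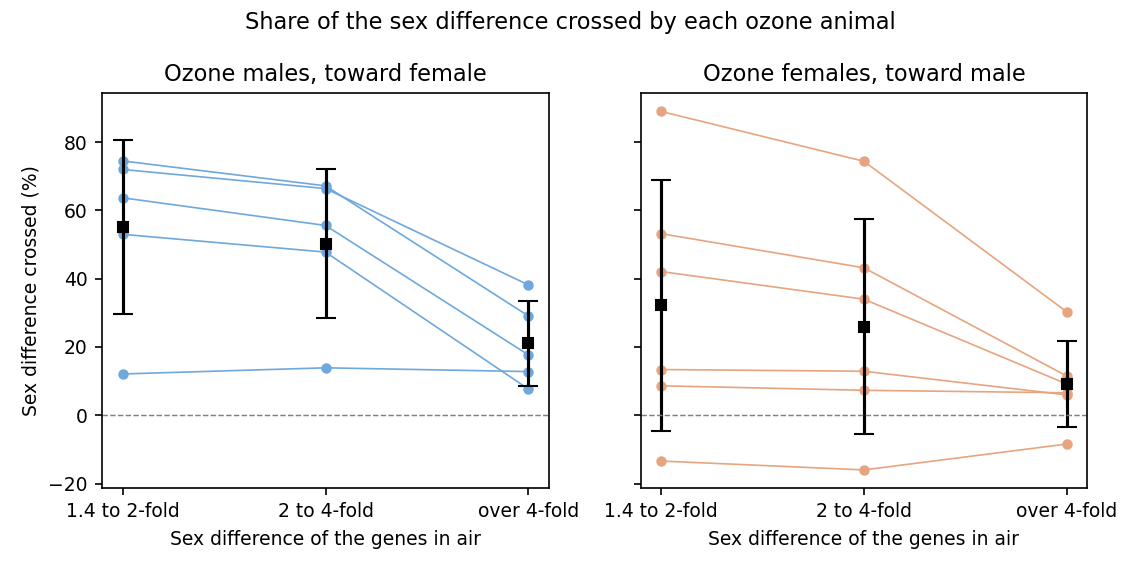
Percent of the sex difference in air that each ozone animal had crossed toward the other sex (vertical), for genes in 3 bins of sex difference (horizontal); coloured lines join the values of an animal, and black squares with bars are means and SD (5 males, 6 females). The means fall from 55.1% to 21.1% in males and from 32.2% to 9.18% in females.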

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

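The test of noise in the gene bins, the exact tests of the bins over animals, the permutation of whole animals and the test of the sex score between the sexes were chosen after the results were seen; the other tests of this part were set before. Of 40 groups of values examined for a library far from the rest, 8 had one; chance gives about 1 in 20 for normally distributed values, a rate not shown for the 6 that are CPM of single genes, some near 0. On component 2, male ozone replicate 4 lay at −6.6, with the nearest other ozone male at 29.5. The total count of male ozone replicate 2 was 14098393, with the next at 11272214. ENSRNOG00000007219 stood apart in female air replicate 4 (141.7 CPM, next 21.89), male air replicate 6 (0.3249 CPM, the others 0) and male ozone replicate 1 (72.62 CPM, next 20.24). ENSRNOG00000049893 had 0.2166 CPM in male air replicate 6 (next 0.07909). ENSRNOG00000049422 had 1.421 CPM in female air replicate 2 (next 0.1223) and 0.6141 CPM in male ozone replicate 4 (next 0.08763).

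The effect of maternal ozone differed between the sexes in 1357 genes by the interaction term, and in 986 of these ozone males had also changed. On the axis without a fold limit, the ozone effect on the sex score was 0.73 higher in males than in females (permutation of treatment within sex and sheet, p = 0.0135, 5040 arrangements). The effect was 0.481 in males and −0.249 in females, each toward the other sex, so the difference joins both shifts. Whether males moved further than females was not tested. On the planned axis of at least 2-fold genes the difference was 0.245 (permutation p = 0.0609).

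Nearly all genes called in ozone males that also differed by sex had moved toward the female level. Mixing or exchange with female RNA is argued against: genes seen only in air females reached a median of 1.117% of the female air level in ozone males, although this rests on 4 genes, and ENSRNOG00000049893, with shared reads, reached 62.3%. The sample sheet was a term of the fit that called 1661 genes, so a constant sheet effect is argued against as the whole cause. The values within sheet 1 cannot decide. There 91.3% of sex-dependent genes moved toward the female level, but its air males also entered the sex calls. Within that sheet 9 genes were called. Without male ozone replicate 2, the only ozone male of sheet 2, 108 genes were called. A general axis of variation between livers stays open: the main axis within the female groups correlated across genes with the male ozone effect at an absolute r of 0.655 (0.325 for air females alone and 0.657 for ozone females alone). The female and male groups share no library, but the female livers helped to estimate the sheet term of the fit that gave the male effect. With whole animals permuted the share of genes moving toward the female level did not pass (exact permutation p = 0.0571). The planned sex score, permuted likewise, did not pass on the axis of at least 2-fold genes (exact permutation p = 0.129). It passed without a fold limit (exact permutation p = 0.0214). These tests cannot tell causes apart, since they compare only the treatment labels. Given the axis within females, part of the male shift may lie along a state that livers enter for reasons other than exposure. Litter, feeding, handling and tissue sampling are possible reasons, and none was tested. The maternal exposure stays open as the biological explanation, since what else differed between the exposure groups was not tested.

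Genes with a large sex difference had crossed a smaller part of it than genes with a modest one in 9 of the 11 ozone animals (exact permutation p = 0.00586), although neither sex passed alone (p = 0.125, where 5 males allow no p under 0.0625, and p = 0.0938). Expression level is argued against as the cause: among genes of low, middle and high mean expression, the share crossed by genes over 4-fold in males was 47.6%, 33.7% and 23.9% of that of 1.4 to 2-fold genes. Noise in the binning is argued against by the design of the measure: the bins were set on libraries that entered neither difference, where noise would leave equal shares, and the share of genes over 4-fold was 38.3% of that of 1.4 to 2-fold genes. Genes seen in 1 sex alone were not set apart from the other genes over 4-fold, so their part in the smaller share is not known. No biological explanation was tested.

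Other groupings of the same animals were fitted to see whether chance can be excluded, with 100 groupings per comparison, the real one included. For ozone in males 1 of 100 gave as many calls (real 1661, highest other 97), and for sex in air 1 of 100 (real 6183, highest other 4449). For the interaction 1 of 100 did as well (real 1357, highest other 3). These counts stood apart from such groupings, which were not kept within sheets or litters. For the male shift, permutations of males within sheets were divided. The share of genes moving toward the female level did not pass (exact permutation p = 0.0571). The sex score did not pass on the axis of at least 2-fold genes (exact permutation p = 0.129) but passed without a fold limit (exact permutation p = 0.0214). The interaction count was 0 without female air replicate 2, male air replicate 6 or male ozone replicate 2. That loss shows dependence on single animals and does not test chance. Chance is not excluded for ozone in males, where the permutations within sheets were divided. Nor is it excluded for the interaction, whose other groupings were not kept within sheets or litters. For sex in ozone offspring 2 of 100 gave as many (real 776), but 16 of the other groupings gave some calls and the highest of them, 1187, exceeded the real count, so this count does not stand as clearly apart. The grouping with 1187 calls set 4 of the 5 ozone males with female ozone replicates 2 and 6 against the other animals, and both sheets were on both sides. For ozone in females the real count was 0, so all 100 had to give as many and nothing follows from that. Among the others, 5 gave some calls, up to 2222, which points to a structure among the females other than the exposure; the grouping with 2222 calls had 3 animals of each sheet on both sides.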

How the results depend on the processing

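Sheet 1 alone for the sex difference and for the sex scores, and the axis without both fold limit and sheet, were added after the data were seen; all other settings were planned. No result reversed. The direction of each sex score difference held in all settings. For females no setting passed, but sheet 1 alone and leaving out female air or female ozone replicate 2 allow no p under 0.167. Genes changed in males numbered 1068 at 1.5-fold or more, 3813 with voom quality weights and 9 in sheet 1 alone (7 libraries), and 108 to 3129 with single libraries left out. For females DESeq2 called 7, every other setting and every left-out library 0. Sex in air gave 4082 genes at 1.5-fold or more, 5211 to 6295 with libraries left out. Sex in ozone offspring gave 340 from the ozone groups alone, and 389 to 854 with libraries left out. The interaction gave 886 without a filter, 3108 without the sheet term, 3092 with voom and 2164 with DESeq2, and 0 to 2729 with libraries left out. The male sex score difference was 0.481 without a fold limit and 0.514 without fold limit or sheet (exact p = 0.00433), both past the threshold, and 0.089 to 0.184 with libraries left out. The female one was −0.249 without a fold limit, −0.144 without the sheet, −0.307 without both, and −0.137 to −0.083 with libraries left out. The covariance was 0.2511 with shared controls. Apart from thresholds and smaller sets of libraries, the cause was not tested. No paired analysis was possible because the labels give the groups no shared replicate numbers. The gene list tests and the score on fixed gene lists were not run, since no identifier could be paired with a symbol. At the depth and spread of these libraries, 31.3% of simulated 1.5-fold changes in males and 14.9% in females were called; depth was not varied on its own.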

Other observations

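The tests of this part on the share of abundant genes along the female axis were chosen after the axis had been seen; the test without the most abundant genes was set before its result. Ozone males did not become equal to air females: 1263 genes differed between these groups (edgeR, adjusted p below 0.05). Of the 1489 genes that had changed toward the female level in ozone males, 48 still differed from air females. The 1489 were selected for a clear male change, and a missing call is not equality, so the rest need not have reached the female level. With gene bins set on other libraries, ozone males had crossed 55.1%, 50.2% and 21.1% of differences of 1.4 to 2-fold, 2 to 4-fold and over 4-fold. A small set went beyond both sexes in air: 28 genes were higher and 10 lower in ozone males than in both air males and air females, and 35 of these had no sex call in air.

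The main axis of variation within the female groups held 29.6% of their within-group variance and correlated across genes with the sex difference in air at an absolute r of 0.585. A hypothesis was that this axis follows the share of counts taken by the 10 most abundant genes. Over the 12 females, with group means removed, livers further toward the female end had a smaller share (Pearson r = −0.67, permutation p = 0.017, 0.034 adjusted over 2 relations; Spearman rho = −0.72, permutation p = 0.010). Without the 2 libraries farthest from the median share r was −0.59, and within sheets 1 and 2 it was −0.83 (exact p = 0.040) and −0.64 (exact p = 0.18, n = 6 each). The axis may therefore be tied to how much of the RNA a few abundant transcripts occupy; the relation with the total count was weaker (r = 0.46, permutation p = 0.14).

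A related hypothesis, that a few abundant genes taking counts from the rest produced the shift of ozone males, was tested by removal of the 50 most abundant genes (41.9% of counts) before scaling. The share of sex-dependent genes moving toward the female level was then 92.4%, and 1717 genes changed in males. The shift thus did not depend on those 50 genes. The TMM factors of the main fit already offset such a loss of counts, so the removal could change little. This test therefore cannot decide on the hypothesis.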
